A study of Mus musculus with 80 samples.

How the data were processed

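RNA of liver nuclei was sequenced from female mice of 2 lines, 1 with a nuclear tag in hepatocytes and 1 with a nuclear tag in macrophages. Tagged nuclei were isolated by immunopurification, and total nuclear RNA was made into strand-specific libraries without selection for polyadenylated RNA and sequenced as paired reads of 50 bases. The series has 80 libraries: 32 of tagged hepatocyte nuclei, 32 of tagged macrophage nuclei, and 16 of unpurified liver nuclei, each of these a pool of 4 mice. Each cell type has 8 groups of 4 tagged libraries, fed and fasted at 3, 8, 16 and 24 h. All columns of the tables were matched to samples by their titles.

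The deposited files comprise 1 table of raw read counts per gene for all 80 libraries and, for each cell type, a table of a subset of genes. In the authors' subset tables, the signal per library is the raw count divided by 1 size factor per library, and the tables also give log2 fold changes of fasted over fed mice and an adjusted p-value per gene and time. How the subset of genes was chosen is not given in the sources used here. The submitters' processing notes name STAR 2.4.2a, DESeq2 1.24.0 and the mouse build mm10. The counting tool, and whether counting used the strand, are not given in the sources used here. Length in the table equals gene end minus start, so whole gene bodies with introns are listed, and reads of genes that overlap, or of close paralogs such as the Cyp4a, Acot, Gbp, Saa, Mup, H2 and Mt families, cannot be told apart. Coordinates were checked against GENCODE vM21: 96.8% of the symbols were found there, of which 99.7% overlapped the listed position.

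Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed by filterByExpr (count minimum 10, total minimum 15), libraries were scaled by TMM, and a robust quasi-likelihood F-test was applied with Benjamini-Hochberg adjustment at 0.05. The standard error of a log2 fold change was taken from the F statistic. Fasting was tested at each time against fed libraries of the same time, in a fit to all 32 tagged libraries of the cell type. An F-test over the 4 fasting contrasts asked whether the effect differs between times, and an F-test over the 4 fed groups asked for time of day. The difference between cell types was the difference of the fasting effects in a fit to all 64 tagged libraries. Tagged nuclei were compared with unpurified liver within conditions, 32 against 8 libraries per line. Unpurified liver was tested for the mean fasting effect over the 4 times, with line as a term. CPM are counts scaled to the library total, given as mean and SD over libraries. Replicates are numbered within groups in the order of their accession, and the labels do not pair them between groups. In macrophage-tagged libraries equal numbers belong to the same run of 8 consecutive library numbers.

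Gene lists, named-gene rules, tests and alternatives were fixed before the data were examined, except where a choice is said to have been made later. The 30 lists hold hepatocyte, Kupffer cell and macrophage, monocyte and neutrophil, sinusoidal endothelial, stellate cell, cholangiocyte and lymphocyte markers. They also hold genes of gluconeogenesis, fatty acid oxidation and ketogenesis, fatty acid and triglyceride synthesis, cholesterol synthesis, cholesterol efflux and LXR targets, glycolysis, amino acid catabolism and the urea cycle, bile acid metabolism, autophagy and lysosome, the circadian clock and the cell cycle. The others are targets of the glucocorticoid receptor, of FoxO factors, and of growth hormone and STAT5, the amino acid response through ATF4, endoplasmic reticulum chaperones, heat shock, immediate early genes, acute phase response, inflammatory cytokines and NF-kB targets, interferon response, antigen presentation, and phagocytosis and complement receptors. Each list was tested at each time by camera of limma 3.58.1 with a preset correlation of 0.01 between genes, 120 tests per cell type adjusted together, and again with the correlation estimated from the data. Member counts are given over all genes tested and adjusted over the list alone. The genes named are, per cell type and time, the 3 highest and 3 lowest log2 fold changes among called genes with a mean of at least 1 CPM, no overlap between fasted and fed libraries, a described symbol and selectivity for the cell type, all members of 2 fasting panels, and up to 4 called members per list at its time with the most calls. For enrichment these are the 8 highest and the markers, for differences between cell types the 2 highest and 2 lowest with the panels, and for time effects the 4 smallest p-values with clock genes. Examples were taken from these, and the results of 5 of these genes are not reported here.

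Selectivity for macrophages means higher in tagged nuclei than in unpurified liver with an edgeR adjusted p under 0.05 and a log2 difference above 1, and selectivity for hepatocytes means not lower with a log2 difference under -0.5. The share of hepatocyte RNA in macrophage-tagged libraries was estimated as the median ratio of hepatocyte marker CPM to the mean of hepatocyte-tagged libraries of the same time and feeding state. It was taken per library, compared between fasted and fed libraries by 2-sided permutation tests, and taken again from group means. For this share and the changes predicted from it, counts were scaled to the library's own total without TMM factors. The hepatocyte-tagged libraries come from the other line.

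Alternatives were RLE scaling, no filter on low counts, DESeq2 1.42.0 in place of edgeR, a term for runs of consecutive library numbers, a fit to the 8 compared libraries alone, tests of cell-selective genes alone, and leaving out each library in turn. Scaling on macrophage-enriched genes, and a test of genes to which hepatocyte RNA carried over could give under 10 percent of the level, were added after seeing the data. Feeding, time or fraction labels were also regrouped among the same libraries, in all 35 splits of 4 and 4 libraries or in 100 drawn splits.

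Every main fit, with edgeR and with DESeq2, was tested on simulated data in which 200 genes per comparison, and 800 for the difference between times, were changed by 1.5, 2 or 3-fold. At 2-fold, edgeR recovered 65.7% to 85.1% of changed genes in the fasting comparisons and 43.3% to 46.3% in the differences between cell types, and 0.538% to 10.8% of all calls over the comparisons were false, against 5.56% to 22.8% with DESeq2. The simulated changes were balanced between higher and lower, and the hepatocyte share was not varied. These rates therefore do not cover shifts in composition between fasted and fed libraries. No 2 libraries compared for duplication held identical counts, in 96 pairs. The 16 pools were not tested at single times, since there was 1 per condition and line. The labels give no replicate numbers. In macrophage-tagged libraries each run of 8 consecutive library numbers holds 1 library of each group, and what the libraries of a run share is not given in the sources used here.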

Results

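Nuclear RNA was sequenced from the livers of female mice of 2 lines. In the hepatocyte line a purification tag sits on the nuclear envelope of hepatocytes, the liver's main metabolic cells, and in the macrophage line it sits on that of liver macrophages, most of which are Kupffer cells. Tagged nuclei are captured on beads, so that RNA of 1 cell type is enriched without dissociating the tissue. The design asks how hepatocytes and macrophages of the same organ respond to food withdrawal over time, apart from the daily rhythm of feeding and light. Mice were fasted from zeitgeber time 12, the start of the dark phase, and livers were taken after 3, 8, 16 and 24 h, at zeitgeber times 15, 20, 4 and 12. Fed mice were killed at each of these times as controls. Each of the 16 groups of tagged nuclei held 4 libraries, 64 in all. A further 16 libraries held unpurified liver nuclei, each a pool of 4 mice, with 1 pool per condition and line. The table listed read counts for 20105 genes. Totals per library were 12597786 to 30089561 counts for hepatocyte-tagged nuclei, 14968505 to 44694933 for macrophage-tagged nuclei, and 13246494 to 35514304 for the pools. The labels do not state how many mice each tagged library holds, so p-values measure the spread between libraries. Changes below are log2 fold changes of fasted over fed libraries of the same time with their standard errors, 4 against 4 libraries, and coordinates are those of mouse build mm10.

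Purification of hepatocyte nuclei lowered most markers of other liver cells and left those of hepatocytes nearly level with unpurified liver. All 20 sinusoidal endothelial markers were lower in the 32 tagged libraries than in the 8 pools, with a median log2 difference of -2.53. Of the Kupffer cell and macrophage markers, 24 of 28 were lower (median -2.28), as were 14 of 14 lymphocyte, 19 of 20 stellate cell and 6 of 7 monocyte and neutrophil markers. Stab2, a scavenger receptor of sinusoidal endothelium, differed by -2.60 ± 0.09, and Clec4f, a lectin receptor of Kupffer cells, by -2.57 ± 0.09 (edgeR adjusted p at most 1.55e-23). Hepatocyte markers had a median difference of 0.23, with 6 of 23 higher, and albumin (Alb) had -0.06 ± 0.21, which did not pass the test. Cholangiocyte markers were lower by less, with a median of -0.33, 5 of 12 lower and 1 higher. The highest differences were small: 0.90 ± 0.24 for Pld6, 0.75 ± 0.18 for Spsb2, which overlaps Tpi1 in the genome, 0.74 ± 0.22 for Rapgefl1 and 0.67 ± 0.17 for the retinol dehydrogenase gene Rdh1. In all, 3779 genes were higher and 2684 lower of 13065 tested, none of the higher ones by more than 2-fold. That balance depends on the processing. With RLE scaling 2962 were higher and 2757 lower. Without a filter on low counts these were 2934 and 3731, and with DESeq2 3135 and 3543.

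Purification of macrophage nuclei raised all 29 measured Kupffer cell and macrophage markers, by a median of 12.3-fold. Clec4f was at 1014 ± 234 CPM (counts scaled to the TMM-adjusted library total, mean and SD) in the 32 tagged libraries and at 49.6 ± 8.75 in the 8 pools, a log2 difference of 4.37 ± 0.14. Vsig4, a complement receptor, differed by 4.40 ± 0.16, and Csf1r, the receptor of the macrophage growth factor, by 4.31 ± 0.12 (edgeR adjusted p at most 1.12e-23). Monocyte and neutrophil markers rose in 6 of 8 cases, with a median of 7.85-fold. The highest differences belonged to Cryba4 (5.30 ± 0.50), Plekhg4 (5.09 ± 0.48), Shcbp1l (4.73 ± 0.37), Mybpc1 (4.69 ± 0.33), the lectin gene Cd209g (4.66 ± 0.38), Dnajb13 (4.65 ± 0.18), the chemokine gene Ccl3 (4.63 ± 0.49) and Naip7 (4.62 ± 0.27), with edgeR adjusted p at most 1.22e-10. Plekhg4 overlaps Kctd19 and Naip7 overlaps Naip6, and reads of such neighbours are not told apart where the counting ignores strand. Hepatocyte markers fell in all 23 cases but only to a median of 0.431 of their level in unpurified liver: Alb was at 1865 ± 884 CPM in tagged nuclei and 4303 ± 1806 CPM in the pools. Endothelial markers were at a median of 0.367 of the pools' level, stellate markers at 0.480 and lymphocyte markers at 0.447. Some members went the other way: 4 of 20 endothelial, 1 of 20 stellate and 2 of 19 lymphocyte markers were higher in tagged nuclei. The 2337 genes higher in tagged nuclei by more than 2-fold are called macrophage-enriched below.

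After 3 h without food, hepatocyte nuclei held more RNA of metallothionein, gluconeogenesis and fatty acid oxidation genes and less of cholesterol and fatty acid synthesis genes. The metallothionein genes Mt2 (chromosome 8, 94172618 to 94173567) and Mt1, whose products bind zinc and copper, rose by 8.62 ± 0.83 and 7.48 ± 0.79, Mt2 from 0.377 ± 0.232 to 151 ± 52.4 CPM. Ppp1r3g, a regulator of glycogen synthesis, rose by 7.44 ± 1.14. The 3 lowest were Mvd of the mevalonate pathway (-4.76 ± 0.38), the water channel gene Aqp8 (-5.04 ± 0.59) and the phosphate transporter gene Slc34a2 (-5.15 ± 0.89). The edgeR adjusted p was at most 4.35e-05 for these 6. Of 12942 genes tested, 2519 rose and 2639 fell.

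Among genes of gluconeogenesis, 11 of 20 measured members rose and 1 fell (14 and 1 adjusted over the list alone), including Pck1 (3.34 ± 0.55), the gene of its rate-limiting enzyme, Ppargc1a (2.41 ± 0.55), a coactivator induced by fasting, and G6pc (1.51 ± 0.50). Of fatty acid oxidation and ketogenesis genes, 39 of 50 measured members rose and 0 fell (40 and 0 adjusted over the list alone). Cpt1a, which admits fatty acids to mitochondria, rose by 2.49 ± 0.23, Cyp4a14 by 4.84 ± 0.49 and Pdk4 by 2.76 ± 0.50. In cholesterol synthesis, 24 of 26 measured members fell and 1 rose (24 and 1 adjusted over the list alone): Mvk fell by 3.93 ± 0.36 and Fdps fell by 3.77 ± 0.33. Fatty acid and triglyceride synthesis genes went the same way: 15 of 26 measured members fell and 2 rose (15 and 2 adjusted over the list alone), with Fasn at -3.88 ± 0.52 and Scd1 at -3.59 ± 0.54. The camera adjusted p was 1.16e-04, 8.89e-18, 1.57e-14 and 5.97e-05 for these 4 lists, and adjusted p = 0.149, 0.120, 0.120 and 0.294 with an estimated correlation.

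Hormone-responsive lists rose at 3 h. Of glucocorticoid receptor targets, 23 of 29 measured members rose and 1 fell (24 and 1 adjusted over the list alone), among them Fam107a (6.94 ± 1.05), Fkbp5 (4.47 ± 0.50) and Cdkn1a (4.76 ± 0.74), with camera adjusted p = 9.62e-09, and adjusted p = 0.206 with an estimated correlation. Of FoxO targets that insulin represses, 17 of 24 measured members rose and 2 fell (18 and 3 adjusted over the list alone): Igfbp1 rose by 5.63 ± 1.03, Txnip by 4.04 ± 0.44 and Irs2, which carries the insulin signal, by 2.24 ± 0.37, with camera adjusted p = 2.62e-06, and adjusted p = 0.204 with an estimated correlation. Among immediate early genes, 10 of 19 measured members rose and 1 fell (11 and 1 adjusted over the list alone), led by Maff (3.71 ± 0.38) and Egr1 (3.71 ± 0.75), with camera adjusted p = 0.00274, and adjusted p = 0.337 with an estimated correlation. Autophagy and lysosome genes rose in 18 of 30 cases and fell in 2 (20 and 4 adjusted over the list alone), among them Gabarapl1 (2.67 ± 0.33) and Map1lc3b (2.62 ± 0.30), with camera adjusted p = 1.71e-05, and adjusted p = 0.120 with an estimated correlation. Endoplasmic reticulum chaperone genes fell: 17 of 23 measured members fell and 2 rose (18 and 2 adjusted over the list alone), with Sdf2l1 at -4.11 ± 0.67 and Manf at -2.88 ± 0.47, while Herpud1 rose by 2.59 ± 0.39 (camera adjusted p = 2.44e-05, and adjusted p = 0.388 with an estimated correlation). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 3.53 ± 0.66, and Nr0b2, a repressor of Cyp7a1, rose by 1.67 ± 0.59, within a bile acid list of 7 risen and 5 fallen of 20 members. Among markers of other cells, 5 of 12 cholangiocyte markers and 4 of 20 stellate markers fell and 0 rose. Of endothelial markers 1 of 20 rose and 1 fell, and 4 of 26 Kupffer cell and macrophage markers rose and 2 fell.

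**Figure D1:**
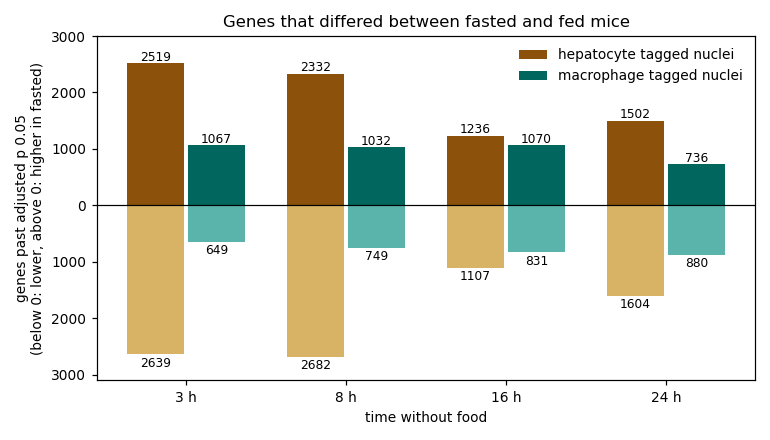
Genes that rose (above 0) and fell (below 0) with fasting at each time in hepatocyte-tagged and macrophage-tagged nuclei, past an edgeR adjusted p of 0.05 with 4 fasted and 4 fed libraries each. Hepatocytes had 5158 such genes at 3 h and 2343 at 16 h, and macrophages 1616 to 1901 at every time.

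At 8 h most fatty acid oxidation genes had risen in hepatocytes, and most interferon response genes had fallen. The highest were Mt2 (6.28 ± 0.79), Fam107a (6.16 ± 1.19), a glucocorticoid-induced gene, and Ppp1r3g (5.50 ± 1.10). The lowest were the plasma glycoprotein gene A1bg (-6.26 ± 1.06), the cytochrome gene Cyp2c69 (from 2176 ± 1352 to 25.3 ± 17.8 CPM) and the steroid dehydrogenase gene Hsd3b5 (-6.82 ± 1.13), which went from 16.4 ± 14.1 to 0.130 ± 0.0565 CPM. The edgeR adjusted p was at most 2.59e-04 for these 6. In all, 2332 genes rose and 2682 fell.

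Of fatty acid oxidation and ketogenesis genes, 45 of 50 measured members rose and 0 fell (46 and 0 adjusted over the list alone), with a median log2 fold change of 1.55. Cidec, a lipid droplet protein, rose by 5.40 ± 0.75, the fasting hormone gene Fgf21 by 4.70 ± 0.51 and Acot1 by 4.13 ± 0.35. In cholesterol synthesis, 24 of 26 measured members fell and 1 rose (24 and 1 adjusted over the list alone) (median -2.77), and of fatty acid synthesis genes 19 of 26 fell and 2 rose (2 and 19 for risen and fallen, adjusted over the list alone). The camera adjusted p was 7.33e-27, 2.31e-18 and 1.04e-07 for these 3 lists, and adjusted p = 0.0634, 0.0881 and 0.149 with an estimated correlation. Of interferon response genes, 27 of 37 measured members fell and 1 rose (28 and 1 adjusted over the list alone), among them the nucleic acid sensor gene Zbp1 (-4.27 ± 0.41), Gbp7 (-3.06 ± 0.34) and Ifit1 (-2.84 ± 0.37), with camera adjusted p = 1.72e-10, and adjusted p = 0.204 with an estimated correlation. In the antigen presentation list 9 of 20 fell and 0 rose (0 and 10 for risen and fallen, adjusted over the list alone), led by Psmb9 (-2.42 ± 0.36) and Tap1 (-1.40 ± 0.29), with camera adjusted p = 0.00128, and adjusted p = 0.257 with an estimated correlation. Of growth hormone and STAT5 targets, 11 of 20 measured members fell and 3 rose (12 and 3 adjusted over the list alone), with camera adjusted p = 0.0219, and adjusted p = 0.414 with an estimated correlation. The chemokine genes Cxcl10 (-2.73 ± 0.54) and Cxcl1 (-2.65 ± 0.40) fell and the interleukin 1 antagonist gene Il1rn rose by 2.22 ± 0.42, within an inflammatory list of 7 fallen and 3 risen of 22. Kupffer cell markers moved up beside these groups: 8 of 26 rose and 1 fell, with a median of 0.42, Hmox1 at 2.86 ± 0.33 and Clec4f at 0.92 ± 0.20. Lyve1 (2.10 ± 0.47) and 6 of 20 endothelial markers in all rose too.

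**Figure D2:**
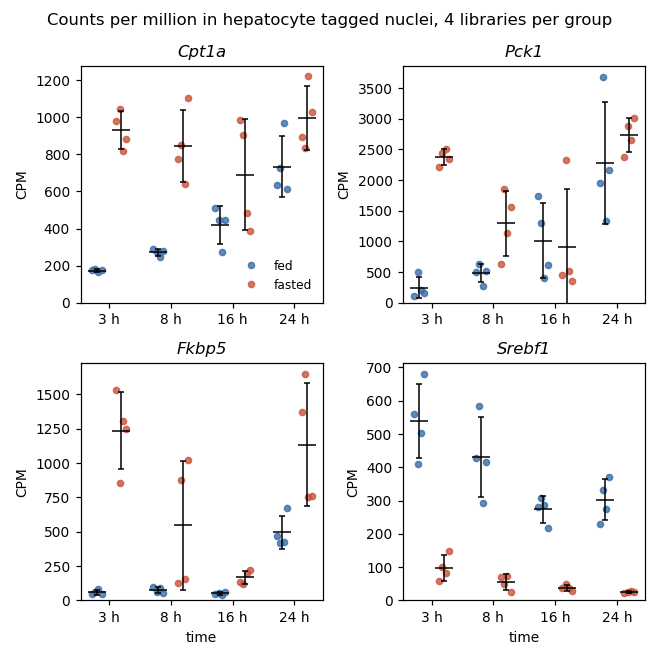
Expression of 4 genes in hepatocyte-tagged nuclei in CPM at 3, 8, 16 and 24 h, with 1 point per library, 4 fed (blue) and 4 fasted (red) per time, and black lines for mean and SD. Cpt1a at 3 h went from 174 ± 7.51 to 932 ± 102 CPM, and Srebf1 from 539 ± 112 to 96.8 ± 38.2 CPM.

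After 16 h, at zeitgeber time 4, fewer hepatocyte genes differed, and the fall of cholesterol synthesis was the widest change. Cidec (5.30 ± 0.73), the trehalase gene Treh (5.11 ± 1.15) and the fatty acid hydroxylase gene Cyp4a14 (4.87 ± 0.49) were highest. Idi1 of the mevalonate pathway (-4.93 ± 0.44), the prostaglandin D synthase gene Ptgds (-6.19 ± 0.50) and the receptor subunit gene Chrna4 (-8.19 ± 1.12) were lowest, and Chrna4 was near the limit of detection in fasted libraries, at 0.108 ± 0.109 CPM. The edgeR adjusted p was at most 0.00250 for these 6. In all, 1236 genes rose and 1107 fell. A fit to these 8 libraries alone called 885 genes, and 1485 were called without fasted replicate 3.

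In cholesterol synthesis, 25 of 26 measured members fell and 0 rose (25 and 0 adjusted over the list alone), with a median of -2.78 and camera adjusted p = 5.57e-37, and adjusted p = 0.0153 with an estimated correlation. In fatty acid oxidation, 36 of 50 measured members rose and 0 fell (40 and 1 adjusted over the list alone): Angptl4 rose by 2.59 ± 0.36 and Fgf21 by 4.60 ± 0.50, with camera adjusted p = 1.39e-20, and adjusted p = 0.0881 with an estimated correlation. Fatty acid synthesis genes fell in 17 of 26 cases and rose in 0 (0 and 21 for risen and fallen, adjusted over the list alone), among them Fasn (-2.75 ± 0.49) and Srebf1 (-2.83 ± 0.30), the regulator of lipid synthesis, with camera adjusted p = 2.60e-13, and adjusted p = 0.0634 with an estimated correlation. Of interferon response genes, 18 of 37 measured members fell and 1 rose (27 and 1 adjusted over the list alone), with camera adjusted p = 1.09e-12, and adjusted p = 0.149 with an estimated correlation. Glycolysis genes moved up in 6 of 21 cases and down in 1 (6 and 2 adjusted over the list alone), with Ldha at 1.29 ± 0.16 and Pfkfb4 at -1.22 ± 0.34 (camera adjusted p = 0.0307, and adjusted p = 0.294 with an estimated correlation). Pck1 (-0.15 ± 0.51, edgeR adjusted p = 0.879) and G6pc (-0.59 ± 0.49, edgeR adjusted p = 0.447) did not pass the test, and of gluconeogenesis genes 4 of 20 rose. Fed Pck1 was at 1015 ± 616 CPM at 16 h against 245 ± 173 CPM at 3 h. Fasted Pck1 was at 910 ± 947 CPM against 2379 ± 130 CPM. Of stellate cell markers 4 of 20 fell, and 1 of 26 Kupffer cell markers rose.

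After 24 h hepatocytes held less RNA of most fatty acid synthesis and interferon response genes, and more of a cell-cycle inhibitor. Cdkn1a, which encodes the inhibitor p21, rose by 5.42 ± 0.84, from 0.393 ± 0.190 to 16.5 ± 4.07 CPM, Fam107a by 5.41 ± 0.97 and Treh by 4.99 ± 1.05. The protease inhibitor gene Serpina9 fell by 5.99 ± 0.93, the organic anion transporter gene Slc22a7 fell by 6.10 ± 0.60 and Chrna4 fell by 8.35 ± 1.15, to 0.0787 ± 0.0557 CPM. The edgeR adjusted p was at most 0.00110 for these 6. In all, 1502 genes rose and 1604 fell.

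Of fatty acid and triglyceride synthesis genes, 22 of 26 measured members fell and 0 rose (22 and 2 adjusted over the list alone): Thrsp fell by 5.15 ± 0.80, Pnpla3 fell by 4.78 ± 0.85, Scd1 fell by 4.40 ± 0.57 and Srebf1 fell by 3.58 ± 0.31, with camera adjusted p = 3.54e-14, and adjusted p = 0.0634 with an estimated correlation. In cholesterol synthesis, 22 of 26 measured members fell and 0 rose (22 and 0 adjusted over the list alone), with camera adjusted p = 1.39e-20, and adjusted p = 0.0634 with an estimated correlation. Among fatty acid oxidation genes, 20 of 50 measured members rose and 6 fell (25 and 6 adjusted over the list alone), fewer than at 3, 8 and 16 h, with camera adjusted p = 2.07e-04, and adjusted p = 0.449 with an estimated correlation. Cpt1a was at 0.46 ± 0.22 (edgeR adjusted p = 0.127), while Cyp4a14 (4.30 ± 0.48) and Fgf21 (3.09 ± 0.57) rose. For Cpt1a the fed level had climbed, with 174, 272, 420 and 734 CPM in fed libraries at 3, 8, 16 and 24 h. Fasted libraries stayed high at 932, 843, 689 and 995 CPM, so its smaller change is not a lower fasted level. Amino acid catabolism genes rose in 12 of 30 cases and fell in 0 (13 and 1 adjusted over the list alone), with camera adjusted p = 5.10e-04, and adjusted p = 0.388 with an estimated correlation. Of interferon response genes, 24 of 37 measured members fell and 0 rose (32 and 0 adjusted over the list alone), with camera adjusted p = 3.25e-14, and adjusted p = 0.125 with an estimated correlation. Some but not most members fell among growth hormone targets (9 of 20), bile acid genes (8 of 20), LXR targets (8 of 18) and acute phase genes (10 of 28). The camera adjusted p of these lists was 8.73e-04, 0.00666, 0.00301 and 0.0118, and adjusted p = 0.294, 0.337, 0.149 and 0.337 with an estimated correlation. Beside these groups 5 of 23 hepatocyte markers fell (median -0.37), and 6 of 20 endothelial markers rose (median 0.47).

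In hepatocytes the fasting effect differed between the 4 times for 4245 genes. Abcg8 and Abcg5, which overlap in the genome and form the sterol exporter, rose early and fell late: Abcg8 changed by 2.83 ± 0.20 at 3 h, 1.84 ± 0.19 at 8 h and -0.70 ± 0.19 at 16 h, and stood at -0.47 ± 0.19 at 24 h (edgeR adjusted p = 0.0653 for that time and 4.19e-10 for the difference between times). Arsg, a lysosomal sulfatase gene that overlaps Slc16a6, went the other way, from -1.33 ± 0.17 at 3 h to 1.51 ± 0.17 at 24 h (edgeR adjusted p = 4.12e-09 for the difference). The clock gene Nr1d2, a repressor, rose by 1.69 ± 0.20 at 3 h and 2.20 ± 0.20 at 8 h and had -0.46 ± 0.19 and -0.24 ± 0.19 later (edgeR adjusted p = 8.46e-08 for the difference), and of 21 circadian clock genes Per2, Nr1d1 and Arntl also differed (edgeR adjusted p = 1.26e-04, 4.26e-04 and 0.00103). In 100 splits of the libraries, feeding labels regrouped within times, the real one included, 1 other called more genes, 4384.

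Time of day alone changed 3899 genes in the 16 hepatocyte libraries of fed mice. The smallest adjusted p belonged to the clock genes Nr1d2 (edgeR adjusted p = 4.06e-12) and Per2 (edgeR adjusted p = 8.41e-12), with Map4k4 also among the 4 smallest (edgeR adjusted p = 4.05e-10). Nr1d2 was at 258 ± 70.3 CPM at zeitgeber time 12 and 19.8 ± 2.48 CPM at zeitgeber time 20, and the activator gene Arntl at 24.1 ± 12.2 and 411 ± 46.2 CPM. Of 21 clock genes 15 passed the test, and Hlf, Nfil3, Bhlhe40, Bhlhe41, Csnk1d and Csnk1e did not (edgeR adjusted p 0.0541 to 0.650).

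In macrophage-tagged nuclei, the fasting comparisons hold both macrophage RNA and hepatocyte RNA, and the estimated share of the latter differed with feeding. Estimated from the 23 hepatocyte markers against hepatocyte-tagged nuclei of the same time and feeding state, which come from the other line, it averaged 57.0% in the 16 fasted and 42.7% in the 16 fed libraries (2-sided permutation p = 1.40e-04). The difference was 4.12 points at 3 h, 27.4 at 8 h, 12.6 at 16 h and 13.1 at 24 h (exact permutation p = 0.514, 0.0286, 0.114 and 0.0286, of which 0.0286 is the smallest that 4 against 4 libraries allow). These p-values leave out the spread of the hepatocyte-tagged libraries, since all 4 libraries of a group were divided by the same mean. A difference between the livers of the lines that varies with feeding would also enter the share. From group means the share was 57.5% fasted and 48.3% fed at 3 h, 61.4 and 38.03% at 8 h, 51.9 and 41.5% at 16 h, and 60.6 and 41.4% at 24 h. Kupffer cell markers had median fasting changes of -0.10, -0.28, -0.19 and -0.15, and hepatocyte markers of 0.28, 0.48, 0.33 and 0.20. Of 13864 genes tested, 1067 rose and 649 fell at 3 h, 1032 and 749 at 8 h, 1070 and 831 at 16 h, and 736 and 880 at 24 h. Among the 2337 macrophage-enriched genes, 96 rose and 143 fell at 3 h, 35 and 341 at 8 h, 50 and 383 at 16 h, and 82 and 413 at 24 h. Scaled on the macrophage-enriched genes, a setting chosen after seeing the data, 846 genes rose and 214 fell at 3 h, 2609 and 246 at 8 h, 2900 and 399 at 16 h, and 1239 and 499 at 24 h. Among macrophage-enriched genes that scaling gave 160 and 83, 175 and 142, 271 and 233, and 275 and 320, so that directions of small changes in these nuclei depend on the scaling. It moved the median change of all genes by 0.10, 0.29, 0.27 and 0.23 and turned the sign of the Kupffer cell marker median at each time.

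Macrophage-enriched genes that rose after 3 h included a lipid mediator hydrolase gene and an adhesion gene. Pla2g7, which encodes the hydrolase of platelet-activating factor, rose by 2.86 ± 0.30 (chromosome 17, 43568451 to 43612201), from 16.7 ± 6.33 to 122 ± 53.4 CPM, the adhesion molecule gene Vcam1, which endothelium also expresses, by 2.52 ± 0.43 and the G protein regulator gene Rgs1 by 2.41 ± 0.63. Tmem40 (-1.51 ± 0.50), the creatine kinase gene Ckb (-1.58 ± 0.37) and the lectin gene Cd209g (-1.58 ± 0.38) were lowest. The edgeR adjusted p was at most 0.0438 for these 6. The scavenger receptor gene Cd163 rose by 1.47 ± 0.25, and Clec4f (-0.21 ± 0.19) and Marco (0.04 ± 0.46) did not pass the test. Beside these genes 4 of 20 endothelial markers rose and 0 fell (median 0.25), with a sum of 1758 ± 273 CPM in fed and 2574 ± 542 CPM in fasted libraries. That sum does not measure endothelial RNA alone, since it lies above the 1520 and 1732 CPM of the line's fed and fasted pools. Of the 20 markers, 4 were higher in tagged nuclei than in the pools, and Mrc1 is also on the Kupffer cell list. Of glucocorticoid receptor targets, 18 of 30 measured members rose and 0 fell (22 and 0 adjusted over the list alone): Fkbp5 rose by 3.86 ± 0.47, Zbtb16 by 3.83 ± 0.57, Klf9 by 1.55 ± 0.20 and Tsc22d3 by 1.71 ± 0.39, with camera adjusted p = 1.55e-15, and adjusted p = 0.0730 with an estimated correlation. FoxO targets rose in 10 of 24 cases and fell in 0 (14 and 0 adjusted over the list alone), led by Igfbp1 (4.22 ± 0.88) and Lpin1 (3.78 ± 0.41), with camera adjusted p = 8.18e-09, and adjusted p = 0.0669 with an estimated correlation. Of members not enriched in macrophages, 23 of 25 glucocorticoid receptor targets and 22 of 23 FoxO targets lay within 2 standard errors of the change that hepatocyte RNA in these libraries would give, but 16 of 26 cholesterol synthesis, 17 of 26 fatty acid synthesis and 23 of 48 fatty acid oxidation genes. A value in that range does not exclude a response of the macrophages themselves. Fasted Fkbp5 at 3 h was at 1393 ± 431 CPM in macrophage-tagged and 1237 ± 281 CPM in hepatocyte-tagged nuclei. Hepatocyte RNA at the estimated share would give only part of that level, though the share was taken without TMM factors and these CPM with them. In cholesterol synthesis, 20 of 26 measured members fell and 1 rose (24 and 1 adjusted over the list alone), and in fatty acid synthesis, 13 of 26 measured members fell and 1 rose (15 and 1 adjusted over the list alone). The camera adjusted p was 5.95e-17 and 7.03e-08, and adjusted p = 0.177 and 0.299 with an estimated correlation. Of fatty acid oxidation genes 15 of 49 rose, beside a hepatocyte marker median of 0.28; of these 3 metabolic lists only 1 measured gene is macrophage-enriched. A fit to the 8 libraries alone called 247 genes, Tmem40, Ckb and Cd209g not among them, and of 58 named results at this time 21 were kept in every planned setting. Without fasted replicate 3, fed replicate 3, fed replicate 4 or fasted replicate 2 the count was 702, 971, 1122 or 2720.

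At 8 h some inflammatory and antigen presentation genes fell in macrophage-tagged nuclei, and fewer did when scaled on macrophage-enriched genes. Mybpc1 (2.24 ± 0.39), Pla2g7 (2.22 ± 0.29) and Ms4a4a (2.14 ± 0.46) were the highest macrophage-enriched genes, and Cass4 (-1.61 ± 0.45), the replication helicase gene Mcm5 (-1.63 ± 0.32) and the nucleotide deaminase gene Dctd (-1.79 ± 0.27) the lowest (edgeR adjusted p at most 0.0170). Of inflammatory cytokine and NF-kB target genes, 7 of 40 measured members fell and 1 rose (8 and 2 adjusted over the list alone): the chemokine gene Ccl2 fell by 1.96 ± 0.46, Ccl7 fell by 1.76 ± 0.46, Tnf fell by 1.42 ± 0.36 and the costimulator gene Cd40 fell by 1.19 ± 0.19, with camera adjusted p = 1.26e-04, and adjusted p = 0.335 with an estimated correlation. Nfkbia, an inhibitor of NF-kB, rose by 0.67 ± 0.21. Of antigen presentation genes, 9 of 20 measured members fell and 0 rose (14 and 0 adjusted over the list alone), among them Ciita (-1.10 ± 0.26), the master regulator of class II genes, and Cd74 (-0.83 ± 0.26), with camera adjusted p = 3.50e-08, and adjusted p = 0.224 with an estimated correlation. Of interferon response genes, 10 of 38 measured members fell and 0 rose (22 and 0 adjusted over the list alone), with camera adjusted p = 8.00e-11, and adjusted p = 0.374 with an estimated correlation. Fkbp5 (3.24 ± 0.46), Zbtb16 (3.31 ± 0.56) and Cd163 (0.98 ± 0.25) rose, within 18 of 30 glucocorticoid receptor targets (camera adjusted p = 1.13e-13, and adjusted p = 0.0980 with an estimated correlation). Of the targets not enriched in macrophages, 24 of 25 lay within 2 standard errors of the change that hepatocyte RNA would give, against 25 of 48 fatty acid oxidation genes. That match does not exclude a response of the macrophages themselves. Among fatty acid oxidation genes, 30 of 49 measured members rose and 0 fell (35 and 0 adjusted over the list alone), with camera adjusted p = 5.04e-18, and adjusted p = 0.224 with an estimated correlation; beside them 8 of 23 hepatocyte markers rose, with Hnf4a at 1.06 ± 0.30, and 4 of 29 Kupffer cell markers fell. Lymphocyte markers had a median of -0.41, with 3 of 17 fallen, and monocyte and neutrophil markers of -0.36. Endothelial markers rose in 6 of 20 cases and fell in 0, with a median of 0.42. Scaled on macrophage-enriched genes, 4 inflammatory genes fell and 3 rose, and 2 antigen presentation and 5 interferon genes fell. Without fasted replicate 3, fed replicate 2 or fed replicate 1 the count of genes was 702, 942 or 1023.

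After 16 h, many interferon response genes and some cell cycle genes were lower in macrophage-tagged nuclei. Pabpc1l (2.25 ± 0.42), Efhc2 (2.21 ± 0.46) and the scavenger receptor gene Marco (1.96 ± 0.47, from 50.5 ± 19.4 to 192 ± 70.8 CPM) were the highest macrophage-enriched genes. Cd163 (-0.22 ± 0.25) did not pass the test. Cd209g (-2.81 ± 0.42), Fignl1 (-2.83 ± 0.52) and Uhrf1 (-3.25 ± 0.45), which maintains DNA methylation at replication, were the lowest (edgeR adjusted p at most 0.00611). Of interferon response genes, 23 of 38 measured members fell and 0 rose (29 and 0 adjusted over the list alone), with a median of -0.72 and camera adjusted p = 1.17e-16, and adjusted p = 0.266 with an estimated correlation. Among cell cycle genes, 10 of 30 measured members fell and 0 rose (16 and 0 adjusted over the list alone), with a median of -0.93 and camera adjusted p = 1.52e-08, and adjusted p = 0.335 with an estimated correlation. Scaled on macrophage-enriched genes, 17 interferon and 9 cell cycle genes fell. Of inflammatory genes 5 of 40 rose and 1 fell, and 12 rose and 1 fell with that scaling. In cholesterol synthesis, 24 of 26 measured members fell and 0 rose (24 and 0 adjusted over the list alone), with Sqle at -4.26 ± 0.52, Fdps at -4.13 ± 0.44 and camera adjusted p = 1.24e-37, and adjusted p = 0.0455 with an estimated correlation. Of fatty acid oxidation genes, 34 of 49 measured members rose and 0 fell (41 and 0 adjusted over the list alone), including Cidec (7.06 ± 1.47) and Angptl4 (3.43 ± 0.45), with camera adjusted p = 1.05e-22, and adjusted p = 0.181 with an estimated correlation. Of members not enriched in macrophages, 7 of 26 cholesterol synthesis genes and 48 of 48 fatty acid oxidation genes lay within 2 standard errors of the change that hepatocyte RNA would give. Folr2 (-1.38 ± 0.26) and Fcna (-1.35 ± 0.31) fell among 3 of 29 Kupffer cell markers, and 4, including Cd14 (1.11 ± 0.38), rose. Hepatocyte markers had a median of 0.33, 4 of 20 stellate markers fell, and of 17 lymphocyte markers 3 rose and Bank1 fell (median 0.66). The lymphocyte marker sum went the other way than that median, from 1282 ± 244 CPM in fed to 640 ± 118 CPM in fasted libraries. Of monocyte and neutrophil markers 2 of 8 fell and 0 rose (median -0.29). A fit to the 8 libraries alone called 989 genes, and without fasted replicate 1, fed replicate 4 or fed replicate 1 the count was 922, 1168 or 1187.

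After 24 h, most cell cycle and interferon response genes had fallen in macrophage-tagged nuclei. Of cell cycle genes, 25 of 30 measured members fell and 1 rose (28 and 1 adjusted over the list alone), with a median of -1.93: the spindle checkpoint kinase gene Bub1 fell by 4.43 ± 0.58, Top2a fell by 3.72 ± 0.44, from 25.7 ± 14.6 to 1.96 ± 0.429 CPM, Ccnb1 fell by 3.58 ± 0.69 and Kif4 fell by 3.45 ± 0.45. Cdkn1a was the 1 member that rose. Of the 20 macrophage-enriched members 19 fell. The list had camera adjusted p = 1.94e-22, and adjusted p = 0.112 with an estimated correlation. Interferon response genes followed, as 34 of 38 measured members fell and 0 rose (37 and 0 adjusted over the list alone), with a median of -1.21; Ifit1 went from 8.68 ± 4.02 to 1.56 ± 0.25 CPM, Isg15 fell by 2.25 ± 0.45, Oas3 fell by 2.23 ± 0.32 and Ifit2 fell by 2.15 ± 0.29, with camera adjusted p = 8.01e-36, and adjusted p = 0.102 with an estimated correlation. The kinetochore gene Kntc1 (-4.32 ± 0.53), the replication control gene Dtl (-4.35 ± 0.45) and Bub1 were the lowest macrophage-enriched genes, and Ms4a4a (3.04 ± 0.46), the lipid-associated glycoprotein gene Gpnmb (2.54 ± 0.57) and Pla2g7 (2.52 ± 0.29) the highest (edgeR adjusted p at most 0.00312). Marco (1.66 ± 0.46) and Cd163 (0.92 ± 0.25) passed the test, but Marco did not in 4 and Cd163 in 2 of the 8 fits that left out a library of these groups. The glucocorticoid receptor gene Nr3c1 fell by 0.50 ± 0.12. Of fatty acid synthesis genes, 16 of 26 measured members fell and 1 rose (17 and 1 adjusted over the list alone), with Thrsp at -4.23 ± 0.58 and Fasn at -2.68 ± 0.50 (camera adjusted p = 1.05e-11, and adjusted p = 0.193 with an estimated correlation). In antigen presentation, 8 of 20 measured members fell and 0 rose (13 and 1 adjusted over the list alone), with camera adjusted p = 1.22e-05, and adjusted p = 0.299 with an estimated correlation. Beside these groups the lymphocyte marker median was -0.17 and the monocyte and neutrophil median -0.38, with Ccr2 at -1.33 ± 0.30 and Cx3cr1 at -0.65 ± 0.20, and 4 of 20 endothelial markers rose. The lymphocyte marker sum fell more than that median, from 1093 ± 37.3 CPM in fed to 581 ± 112 CPM in fasted libraries. Scaled on macrophage-enriched genes, 24 cell cycle and 34 interferon genes fell, and of antigen presentation genes 4 fell and 2 rose.

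**Figure D3:**
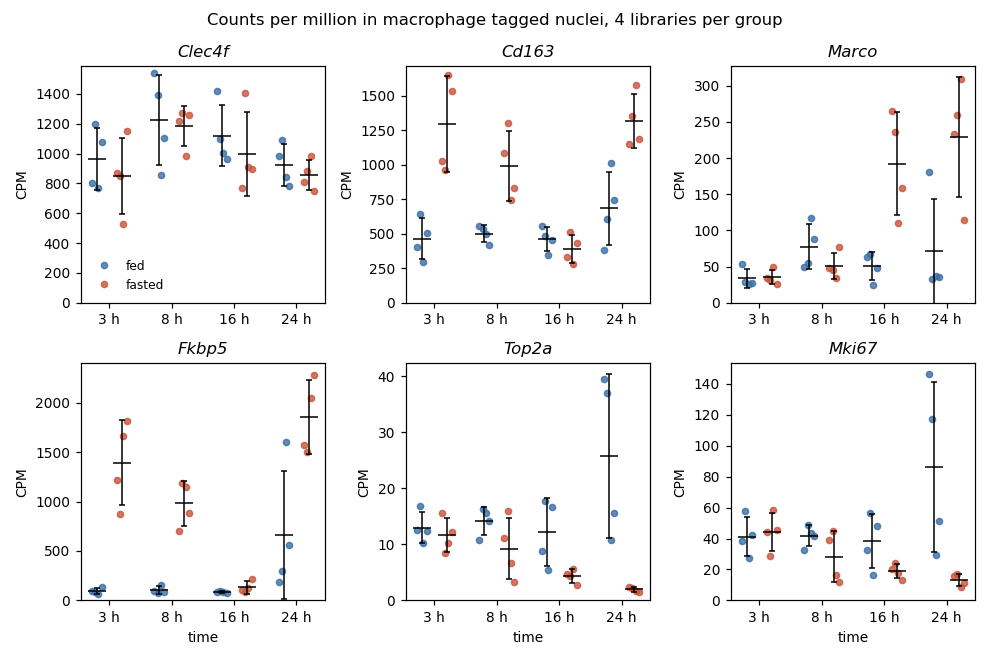
Expression of 6 genes in macrophage-tagged nuclei in CPM at 3, 8, 16 and 24 h, with 1 point per library, 4 fed (blue) and 4 fasted (red) per time, and black lines for mean and SD. Top2a at 24 h went from 25.7 ± 14.6 to 1.96 ± 0.429 CPM, with 2 fed libraries well above the other 2.

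In macrophage-tagged nuclei the fasting effect differed between times for 645 genes. Lpin1, a phosphatidate phosphatase gene, rose by 3.78 ± 0.41 at 3 h and 2.91 ± 0.40 at 8 h and had -0.83 ± 0.37 at 16 h, and Ap3m1 rose by 1.53 ± 0.17 and 1.39 ± 0.17 at 3 and 8 h and had 0.19 ± 0.17 at 16 h (edgeR adjusted p at most 1.42e-04 for the difference). At 24 h the activin receptor gene Acvr2b fell by 1.01 ± 0.14 and Pydc3 fell by 2.54 ± 0.27 (edgeR adjusted p at most 7.47e-04 for the difference). Of 21 clock genes Arntl, Ciart and Usp2 differed between times (edgeR adjusted p = 0.0256, 0.0394 and 0.0464). Time of day changed 1771 genes in fed mice. Nr1d1, Usp2 and Nr1d2 had the smallest p (edgeR adjusted p at most 3.24e-09), followed by Arntl (edgeR adjusted p = 1.13e-08): Nr1d1 was at 60.1 ± 27.2 CPM at zeitgeber time 4 and 2.25 ± 0.708 CPM at zeitgeber time 20. Of 21 clock genes 16 passed the test, and Cry2, Hlf, Rora, Csnk1d and Csnk1e did not.

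**Figure D4:**
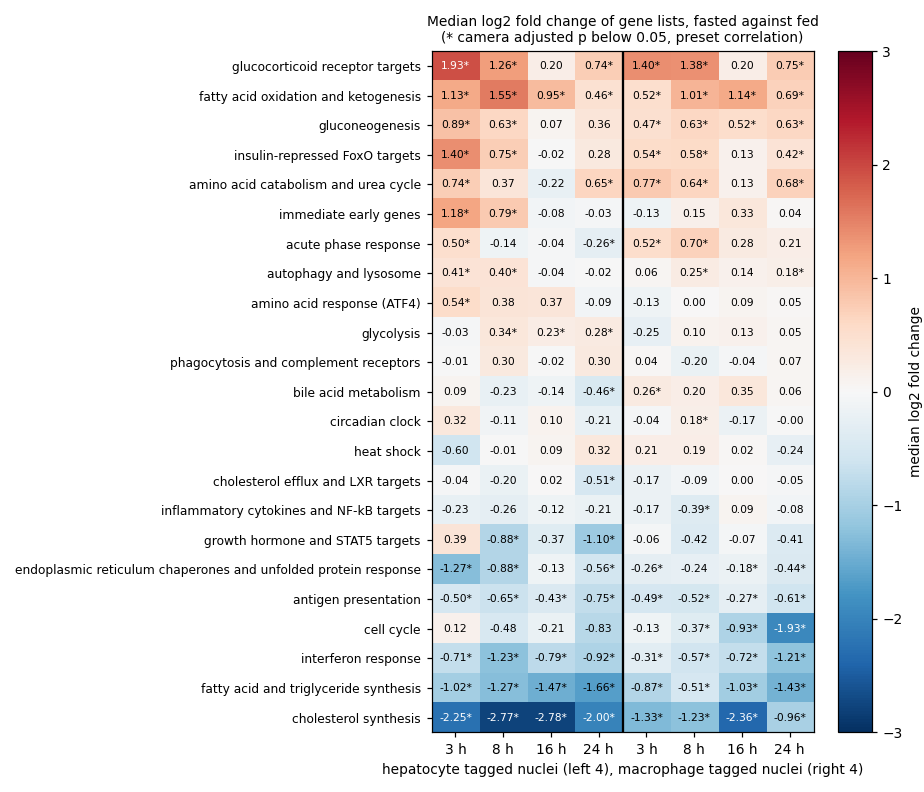
Median log2 fold change of fasted over fed libraries for gene lists (lines of the grid) at 4 times in hepatocyte-tagged (left) and macrophage-tagged nuclei (right), with an asterisk for a camera adjusted p under 0.05 at the preset correlation. Cholesterol synthesis had the lowest medians, -2.78 in hepatocytes and -2.36 in macrophages at 16 h.

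The fasting effects of the 2 cell types were compared directly as a difference of differences. Txnip, an inhibitor of glucose uptake, rose more in hepatocytes by 4.24 ± 0.51 at 3 h and 4.98 ± 0.52 at 8 h (edgeR adjusted p at most 4.36e-07). At 3 h Gadd45g (3.95 ± 0.95), Cpt1a (1.75 ± 0.32) and Nfkbia (1.07 ± 0.27) had the higher effect in hepatocytes, and Rbfox3 (-3.06 ± 0.49), Htra4 (-2.996 ± 0.91), Cyp7a1 (-2.93 ± 0.88) and Scd1 (-2.09 ± 0.64) the lower. At 8 h the effect was higher in hepatocytes for Nr4a1 (3.36 ± 0.98) and Pdk4 (2.64 ± 0.81), and lower for the lectin gene Clec2h (-4.91 ± 1.23), the chemokine gene Ccl9 (-3.54 ± 0.45) and Srebf1 (-1.79 ± 0.48). The Kupffer cell marker Clec4f also differed (1.03 ± 0.29), but it is depleted from hepatocyte-tagged nuclei (9.25 CPM against 53.3 in the pools) and rose there beside other Kupffer cell markers. At 16 h Ppfia4 (3.51 ± 0.66) and Srcin1 (2.51 ± 0.39) were higher, and Hsd17b6 (-2.40 ± 0.50) and Fmn1 (-2.46 ± 0.37) lower. At 24 h the effect on the cell cycle regulator E2f7 (3.58 ± 0.64) and on Pdgfrl (3.83 ± 1.03) was higher in hepatocytes, and that on Clec2h (-4.10 ± 1.02), Arrdc3 (-3.30 ± 0.61) and Abca1 (-0.84 ± 0.25) lower. Ppfia4 and E2f7 are also depleted from hepatocyte-tagged nuclei, by log2 differences of -1.35 and -1.17. The edgeR adjusted p was at most 0.0448 for these genes. In all, 1485, 1068, 75 and 567 of 14011 genes differed at 3, 8, 16 and 24 h. At 3 h 869 effects were higher and 616 lower in hepatocytes, against 684 and 746 with RLE scaling and 849 and 909 with DESeq2. The cell type cannot be separated from the mouse line here. Feeding labels were regrouped within cell types in 100 splits, the real one included. As many genes were called by 4 splits at 3 h, 5 at 8 h, 13 at 16 h and 3 at 24 h. Chance could not be excluded at any of these times.

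Genes called in both cell types moved the same way in nearly all cases. Of 12820 genes tested in both, 736 rose in both at 3 h, where lists of these sizes drawn independently would share 205, and 432 fell in both (independent lists 125). The counts were 732 and 402 at 8 h (185 and 139), 484 and 322 at 16 h (100.4 and 63.7), and 345 and 357 at 24 h (81.9 and 95.1). Genes called in opposite directions numbered 17, 18, 7 and 22. Across genes, fasting effects in the 2 cell types had Pearson's r of 0.643, 0.686, 0.699 and 0.597, and across the 1752 macrophage-enriched genes of 0.368, 0.437, 0.493 and 0.569. Genes are not independent replicates, and hepatocyte RNA in the macrophage libraries enters these values.

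In unpurified liver, fasting was tested once over all times, 8 fasted against 8 fed pools. Cyp4a14 rose by 3.88 ± 0.47, Angptl4 by 2.39 ± 0.32, Igfbp1 by 2.37 ± 0.47, Pdk4 by 2.19 ± 0.49 and Txnip by 1.79 ± 0.35. Fasn fell by 2.74 ± 0.30, Scd1 fell by 2.43 ± 0.31 and Srebf1 fell by 2.35 ± 0.20 (edgeR adjusted p at most 0.00803 for these 8). Macrophage genes of the panel rose for Cd163 (0.64 ± 0.09) and Marco (0.51 ± 0.15) and fell for Timd4 (-0.27 ± 0.06), with edgeR adjusted p at most 0.0208, while Clec4f had 0.02 ± 0.08 (edgeR adjusted p = 0.851). In all, 2224 genes rose and 2509 fell of 13006. Pools of the hepatocyte line alone, 4 against 4, gave 2 genes and those of the macrophage line alone 856, and of the genes named here only Srebf1 was called in both. At single times, with 1 pool per condition and no test, the median change of cholesterol synthesis genes was -2.10, -2.61, -2.25 and -0.84 in the hepatocyte line's pools and -1.68, -1.67, -2.89 and -1.33 in the macrophage line's.

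**Figure D5:**
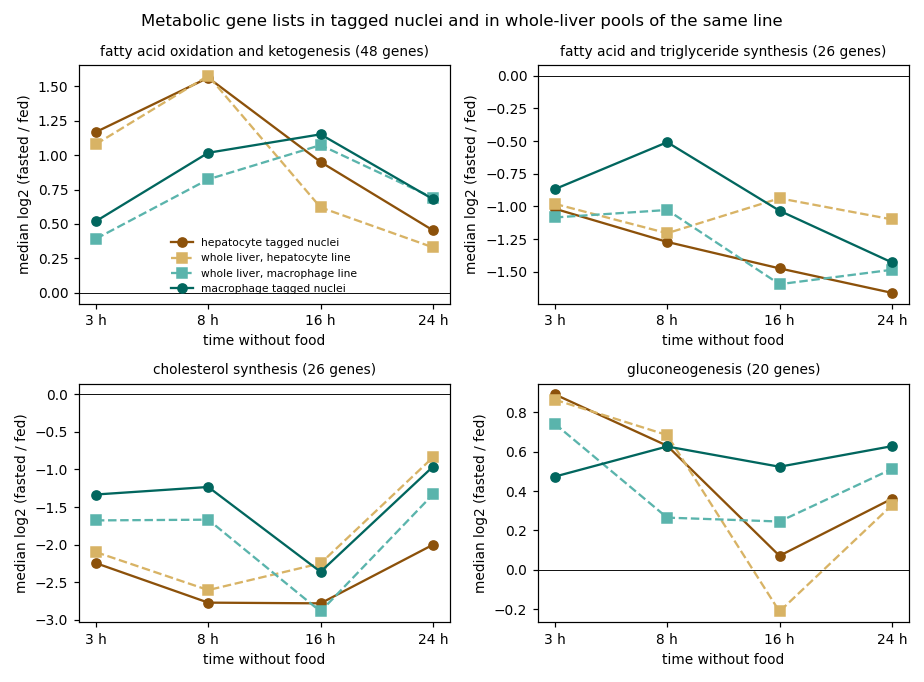
Median log2 fold change of fasted over fed libraries in 4 metabolic gene lists at 3, 8, 16 and 24 h, for tagged nuclei (4 against 4 libraries, solid lines) and unpurified liver of each line (1 pool against 1, dashed lines). At 3 h fatty acid oxidation genes had medians of 1.17 and 1.08 in the hepatocyte line and 0.52 and 0.39 in the macrophage line, tagged nuclei first.

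Over all 30 lists and 4 times, camera called 51 of 120 tests in hepatocytes and 52 of 120 in macrophages with a preset correlation between genes. With the correlation estimated from the data (median 0.158 and 0.219), only the fall of cholesterol synthesis at 16 h kept its call in each, at adjusted p = 0.0153 and 0.0455. In splits of the libraries with feeding labels regrouped within times, a median of 32 list tests in hepatocytes and 37 in macrophages were called, so the number of list calls with a preset correlation says little by itself. The counts of members called gene by gene do not rest on the list tests. But they changed by over 1.5 times, or to or from 0, in 755 of 3904 counts with a library left out, in 136 of 488 from the 8 compared libraries alone and in 88 of 248 scaled on macrophage-enriched genes. Per the authors' deposited table of fold changes and p-values, 1972, 2030, 1027 and 1137 of 4745 genes passed 0.05 in hepatocytes at 3, 8, 16 and 24 h, and 361, 437, 519 and 518 of 3762 genes in macrophages. In the authors' deposited table and in the edgeR test alike, 1881, 1869, 911 and 1043 hepatocyte genes and 287, 376, 447 and 493 macrophage genes passed, all with the same direction in both.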

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

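The tests of dilution and both tests of fewer lymphocytes and monocytes for cell cycle genes, of livers of the same line for metabolic genes, and of line differences for the effects that differ between cell types were chosen only after the result was seen. Among 144 groups of 4 libraries examined for a library far from the others, 6 had one, of which 5 are described here, and chance gives about 1 in 20, or 7.2. Marco was at 53.3 CPM in replicate 1 of fed macrophage libraries at 3 h (25.4 to 28.7 in the other 3) and at 180.15 CPM in replicate 1 at 24 h (33.05 to 37.14). Without the latter the change of Marco at 24 h was 2.68, and without fed replicate 2, fed replicate 3, fed replicate 4 or fasted replicate 3 it was 1.41, 1.45, 1.44 or 1.49 and no longer past the test. Total counts were 42.1 M in replicate 1 of fed macrophage libraries at 8 h (19.3 to 22.2 M). The hepatocyte marker sum was 22297 CPM in replicate 3 of fasted macrophage libraries at 3 h (11013 to 12379). That library also had the fewest genes detected, 13829 (15432 to 15550), and the highest share of counts in its top 50 genes, 14.7% (11.3 to 11.9%), of its group. Its macrophage (12217 CPM), endothelial (3156), stellate (361) and lymphocyte (1742) marker sums were the highest of the group too. All these sums carry the library's TMM factor, so they do not show that it held more of this RNA. Its hepatocyte share, estimated on the library's own total without that factor, was 47.5%, within the range of the others (45.7 to 64.7%). Without this library 702 genes were called in place of 1716. Pck1 was at 2326 CPM in replicate 2 (349 to 515) of fasted hepatocyte libraries at 16 h, and without that replicate Pck1 changed by -1.18 (edgeR adjusted p = 0.0667).

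Cell cycle genes fell in macrophage-tagged nuclei after 24 h. Dilution by RNA of other liver cells is argued against by the 20 macrophage-enriched members, whose median of -2.32 lay below the lowest of 10000 matched random lists of macrophage-enriched genes (-1.17). A high fed group at that time of day is argued against as the whole cause, since the fasted score of 1.39 was below the 2.39 of the 12 fed libraries of the other times (exact permutation p = 5.49e-04). These libraries differ in time of day as well as feeding, so that p-value does not measure fasting alone. Top2a was at 39.54 and 36.96 CPM in fed replicates 1 and 2 at 24 h and at 10.9 and 15.6 CPM in replicates 3 and 4. Fewer lymphocytes and monocytes among the nuclei stay open: their 25 markers had a median of -0.19, but 17 of these are not enriched in the tagged nuclei, and the 8 that are had a median of -0.43 with a bootstrap SE of 0.298, within 2 SE of 0.5 of the cell cycle median (-0.96). Of these 8, Ccr2 (-1.33), Bank1 (-0.999), Plac8 (-0.96) and Cx3cr1 (-0.65) fell (edgeR adjusted p at most 0.0462), and Csf3r (-0.20), Cd79b (-0.19), Itgal (-0.13) and Treml4 (-0.12) did not pass the test (edgeR adjusted p at least 0.629). The lymphocyte marker sum went from 1093 ± 37.3 CPM in fed to 581 ± 112 CPM in fasted libraries at 24 h. With markers this far apart, a loss of such cells and less division among the macrophages cannot be told apart.

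Hepatocyte metabolic genes changed in macrophage-tagged nuclei, where 71.25% of 480 values (bootstrap SE 2.31) lay within 2 standard errors of what carried hepatocyte RNA would give. The share ran from 26.9% for cholesterol synthesis at 16 h, where the median was -2.36 against a predicted -0.99, to 100% for fatty acid oxidation at 16 h, which had 47.9% at 3 h. Carried RNA was predicted to give over the whole measured level of many genes, with a median of 195% for fatty acid oxidation at 3 h, so the prediction is too high there. A share under 75% over all values had been set against this cause, but the prediction used hepatocyte nuclei of the other line, and 75.2% of the values (SE 2.11) lay closer to unpurified liver of the same line, with Pearson's r across values of 0.965 against 0.895. RNA of livers of the same line carried into these libraries is therefore a candidate explanation, least so at 16 h, where the share was 57.5%, below the 60% set for it, against 85, 70 and 88.3% at 3, 8 and 24 h. The same response in macrophages themselves stays open too: 52.9% of 119 genes (SE 4.54) were less depleted from macrophage nuclei than the least depleted hepatocyte marker, close to the 50% set for it, and their median of -1.01 barely differs from that marker's -1.03. The explanations cannot be told apart for these genes, since carried RNA and a response of the macrophages would move them alike.

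The fasting effect differed between cell types for 1485 genes at 3 h, 1068 at 8 h, 75 at 16 h and 567 at 24 h, while cell type and mouse line are confounded. Of the calls on genes not enriched in macrophages, 86.7% of 2553 had the same sign in the difference between the lines' unpurified livers, with a median ratio of 0.40. Of those on macrophage-enriched genes, 66.2% of 642 did, with a median ratio of 0.11. A difference between the livers of the lines and one between the cell types cannot be told apart here, because each cell type comes from 1 line and each line has 1 pool per time and feeding state.

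In 100 splits with feeding labels regrouped within cell types, the real one included, 4 called as many genes at 3 h (highest other 4152) and 3 at 24 h (highest other 1309). These lie under the limit of 0.05, but too close to it, with 100 drawn splits, to exclude chance. With 5 at 8 h (highest other 3296) and 13 at 16 h (highest other 1378) the limit is not met. Splits that call several times the real count point to a structure of the samples: of the other splits with as many genes, 3 of 3 at 3 h, 2 of 4 at 8 h, 8 of 12 at 16 h and 0 of 2 at 24 h had labels mostly swapped in 1 cell type against the other, which turns a shared fasting effect into a difference, so that this accounts for only part of them.

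Genes whose effect differed between cell types, hepatocyte minus macrophage effect, were at 3 h Txnip (4.24), Gadd45g (3.95), Cpt1a (1.75), Nfkbia (1.07), Htra4 (-2.996), Rbfox3 (-3.06), Scd1 (-2.09) and Cyp7a1 (-2.93). At 8 h they were Txnip (4.98), Nr4a1 (3.36), Pdk4 (2.64), Clec4f (1.03), Ccl9 (-3.54), Clec2h (-4.91), Srebf1 (-1.79), Scd1 (-2.77) and Abca1 (-0.82). At 16 h they were Ppfia4 (3.51), Srcin1 (2.51), Hsd17b6 (-2.40) and Fmn1 (-2.46), and at 24 h Pdgfrl (3.83), E2f7 (3.58), Arrdc3 (-3.30), Clec2h (-4.10) and Abca1 (-0.84).

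The effect differed between times for 4245 genes in hepatocytes and 645 in macrophages. In hepatocytes the edgeR adjusted p of that test was 4.19e-10 for Abcg8, 4.12e-09 for Arsg, 6.64e-08 for Abcg5, 8.46e-08 for Nr1d2, 1.26e-04 for Per2, 4.26e-04 for Nr1d1 and 0.00103 for Arntl. In macrophages it was 1.42e-04 for Lpin1 and Ap3m1, 7.47e-04 for Acvr2b and Pydc3, 0.0256 for Arntl, 0.0394 for Ciart and 0.0464 for Usp2. In hepatocytes 2 of 100 splits called as many genes, the real one included (highest other 4384), and in macrophages 1 of 100 (highest other 225). The regroupings argue against chance in macrophages. In hepatocytes the share lies under 0.05, but a regrouping called slightly more genes than the real one, so chance is not excluded.

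For the other counts of genes the regroupings argue against chance as well, but do not exclude it. In the fasting comparisons 1 in 35 is the smallest share that these splits allow. With 35 splits each, 1 split, the real one, called as many genes in every fasting comparison: in hepatocytes 5158, 5014, 2343 and 3106 genes at 3, 8, 16 and 24 h against at most 637, 190, 1110 and 257 in another split, and in macrophages 1716, 1781, 1901 and 1616 against at most 205, 51, 185 and 15. With 100 splits each, 1 reached the real count for time of day (3899 genes in hepatocytes and 1771 in macrophages, highest other 461 and 273), for tagged nuclei against unpurified liver (3779 higher and 2684 lower in hepatocytes, highest other 2365, and 10572 in macrophages, highest other 6318) and for fasting in unpurified liver (4733, highest other 2805). For list tests 4 of 100 splits reached 51 calls in hepatocytes and 3 of 100 reached 52 in macrophages, with 54 the highest other in each. These too lie under 0.05 by too small a margin to exclude chance. Regrouped labels gave a median of 32 and 37 such calls, so the number of list calls says little by itself.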

How the results depend on the processing

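Scaling on macrophage-enriched genes and the test of genes with under 10 percent carried hepatocyte RNA were chosen only after the result was seen. No named gene reversed under any setting run, and of 470 named results past the test 324 were kept in every planned setting, leaving out each library included. These were 72 of 79 in hepatocytes at 3 h, 49 of 58 at 8 h, 17 of 22 at 16 h and 20 of 25 at 24 h, but 21 of 58, 24 of 39, 24 of 39 and 21 of 30 in macrophages at these times and 2 of 29 in unpurified liver. All total counts of genes stayed within 1.5 times the reported ones with RLE scaling and with the term for runs of library numbers, and the exceptions under other settings follow, where the cause was not tested unless named. Without a filter on low counts, 48 genes differed between cell types at 16 h, against 75 reported, and with DESeq2 148. With DESeq2, 1622 macrophage genes differed between times, against 645. Fits to the 8 compared libraries alone, which have fewer libraries to estimate the spread, called 885 genes in hepatocytes at 16 h, against 2343, and 247 and 989 in macrophages at 3 and 16 h, against 1716 and 1901. Tests of macrophage-enriched genes alone, fewer by construction, called 200, 420, 501 and 610 genes at 3, 8, 16 and 24 h, against 1716, 1781, 1901 and 1616, and 10 lists of 56 tests, against 52 of 120. Tests of genes with under 10 percent carried RNA called 139, 313, 321 and 378 at these times, also fewer by construction. Scaling on macrophage-enriched genes gave 1060, 2855 and 3299 genes at 3, 8 and 16 h, of which 79.8, 91.4 and 87.9% were higher in fasted libraries, against 62.2, 57.9 and 56.3% in the reported fit, and at 24 h 71.3% against 45.5%. Pools of the hepatocyte line alone gave 2 genes in unpurified liver and those of the macrophage line 856, against 4733 from all pools. With an estimated correlation 1 list test was called in each cell type, against 51 in hepatocytes and 52 in macrophages.

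Leaving out each library in turn gave 1485 to 2540 genes in hepatocytes at 16 h (2343 with all, 1485 without fasted replicate 3), and in macrophages 702 to 2720 at 3 h, 702 to 1741 at 8 h and 922 to 2270 at 16 h. Libraries that moved these macrophage counts by over 1.5 times were at 3 h fasted replicates 3 (702) and 2 (2720) and fed replicates 3 (971) and 4 (1122), at 8 h fasted replicate 3 (702) and fed replicates 2 (942) and 1 (1023), and at 16 h fasted replicate 1 (922) and fed replicates 4 (1168) and 1 (1187). Time of day in macrophages gave 1134 (without fed replicate 4 at 24 h) to 1721, against 1771 with all. For differences between cell types the ranges were 989 to 1704 at 3 h (989 without fasted hepatocyte replicate 3), 696 to 1162 at 8 h (696 without fed macrophage replicate 1), 24 to 130 at 16 h and 246 to 900 at 24 h, against 1485, 1068, 75 and 567. At 16 h the macrophage libraries were fed replicates 4 (24), 1 (26) and 2 (29) and fasted replicate 4 (46), and the hepatocyte libraries fasted replicates 3 (30) and 2 (130) and fed replicates 2 (31), 4 (37) and 1 (40). At 24 h the hepatocyte libraries were fed replicates 2 (246) and 4 (900) and fasted replicates 1 (302) and 2 (351), and the macrophage libraries fasted replicate 4 (276) and fed replicates 1 (297) and 2 (361). The labels give no replicate numbers to pair libraries by. Runs of consecutive library numbers, which in macrophages hold 1 library of each group, were fitted as a blocked alternative. With that term no total count of genes moved by over 1.5 times (1615 against 1716 in macrophages at 3 h), but 25 of 488 counts of list members did or went to or from 0, and of 421 named fasting results 7 lost and 1 gained the call.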

Other observations

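Of circadian clock genes, 4 of 21 measured members rose and 1 fell (4 and 1 adjusted over the list alone) in hepatocytes at 8 h (camera adjusted p = 0.851, and adjusted p = 0.961 with an estimated correlation), and in macrophages at 8 h 3 of 21 measured members rose and 0 fell (3 and 0 adjusted over the list alone) (camera adjusted p = 0.0466, and adjusted p = 0.564 with an estimated correlation). Heat shock genes at 3 h had a median of -0.60 in hepatocytes, where 5 of 18 measured members fell and 1 rose (5 and 1 adjusted over the list alone) (camera adjusted p = 0.116, and adjusted p = 0.794 with an estimated correlation), and of 0.21 in macrophages, where 3 rose and 0 fell. Of targets of the amino acid response through ATF4, 9 of 22 measured members rose and 5 fell (10 and 5 adjusted over the list alone) in hepatocytes at 3 h (camera adjusted p = 0.0417, and adjusted p = 0.337 with an estimated correlation). Among phagocytosis and complement receptor genes, 2 of 22 measured members fell and 0 rose (2 and 0 adjusted over the list alone) in macrophages at 8 h, with a median of -0.20 (camera adjusted p = 0.0837, and adjusted p = 0.686 with an estimated correlation). In macrophage-tagged nuclei, autophagy and lysosome genes had a median of 0.25 at 8 h, with camera adjusted p = 0.0230, and adjusted p = 0.299 with an estimated correlation, and acute phase genes, which are hepatocyte genes, of 0.70, with camera adjusted p = 1.05e-05, and adjusted p = 0.299 with an estimated correlation.

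Among metabolic lists in macrophage-tagged nuclei, amino acid catabolism genes had a median of 0.77 at 3 h (camera adjusted p = 9.47e-06, and adjusted p = 0.387 with an estimated correlation) and gluconeogenesis genes of 0.63 at 8 h (camera adjusted p = 5.47e-05, and adjusted p = 0.335 with an estimated correlation), beside hepatocyte marker medians of 0.28 and 0.48. Glycolysis genes had a median of 0.10 at 8 h and LXR targets of -0.09, neither past the test (0.748 and 0.707, camera adjusted p). Growth hormone targets had -0.41, bile acid genes 0.06 and endoplasmic reticulum chaperones -0.44 at 24 h, with camera adjusted p = 0.139, 0.647 and 0.00142. Immediate early genes had -0.13 at 3 h, with camera adjusted p = 0.672. The call of chaperones was not kept with an estimated correlation, at adjusted p = 0.616. In hepatocyte-tagged nuclei at 24 h, monocyte and neutrophil markers had a median of -0.06 and lymphocyte markers of 0.16.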
